A study of Homo sapiens with 4 samples.

How the data were processed

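RNA from Raji cells, an established Epstein-Barr virus-positive Burkitt lymphoma line, was profiled on 4 Affymetrix HG-U133 Plus 2.0 arrays. Per the labels, 2 arrays came from a clone in which the long non-coding RNA gene DLEU1 had been downregulated with TALENs, which are designer nucleases that cut DNA at a chosen site, and 2 from a wild-type control clone. Per the labels' protocols, the cells grew in RPMI medium with serum, the RNA was extracted with Trizol and an affinity column, biotinylated cRNA was made from total RNA. The labels give no TALEN target site, so it is unknown whether the DLEU1 probe set lies in an edited part of the gene. The labels name neither a batch nor a date. The kind of duplicate (separate cultures, separate RNA preparations or repeated hybridisation) was not given in the sources used here.

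The authors deposited 1 table with a linear signal intensity for each of 54613 probe sets and 62 control probe sets on every array. Per the submitters' processing notes, the values were made with MAS5, which summarises each probe set on its own array from the perfect-match and mismatch probes. The MAS5 version, its target intensity and its detection calls were not given in the sources used here. The design fixed before the data were examined took the arrays as already scaled by MAS5 to a common target. The deposited values did not bear this out, since the 2% trimmed means ranged from 131 to 197, so there was no common target. The values were still analysed as deposited, as fixed, and the results after quantile normalization are printed beside them for the counts, and at least for each gene list whose count of rises or of falls moved by more than 2.

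Each value was turned into log2(value + 16). Control probe sets were left out of the tests, as were 21845 dim probe sets whose mean log2 value over the 4 arrays lay below the 40th percentile, which left 32768. Group was the only term in the model, and the difference was taken as the DLEU1-downregulated clone minus the control clone. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom came out as infinite, so all probe sets of like brightness shared 1 spread. They were 6.80 after quantile normalization, 6.73 after median centring and 6.62 with a common trimmed mean. The very small p-values as deposited rest on the infinite prior. Among the probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none in the platform annotation of 2016. Symbols were updated through the gene identifier against the RefSeq annotation of GRCh38.p14, which matched 41037 probe sets. That table also gave the order of neighbouring genes, and no coordinates were taken from it because the files name no genome build. A gene was represented by its brightest probe set among those with 1 symbol, which gave 13284 genes.

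The 30 gene lists were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 tested members, and the p-values were adjusted over the lists. For each list the members past the threshold were counted over all probe sets tested and with p adjusted over the list alone. Genes named in the text followed a rule fixed at the same time. It takes DLEU1 and the measured genes of its 13q14 neighbourhood, the 10 largest rises and 10 largest falls among genes past the threshold, and up to 4 members with the smallest p in each list. The largest changes were limited to brightest probe sets that name 1 gene, do not carry the cross-hybridisation suffix _x_at and had groups that did not overlap. Genes named outside this rule are marked as chosen after their values were seen, except those that only mark the ends of a run of neighbouring genes.

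The alternatives were other pseudocounts, other filters on dim probe sets, quantile normalization, median centring, eBayes without a trend, a fit with the replicate number as a term, leaving out each array, leaving out _x_at probe sets, other thresholds, camera with an estimated correlation, limma's fry, and the mean of a gene's probe sets. Scaling to a common trimmed mean, quantile normalization with an estimated correlation, quantile normalization without the dimmest array, and leaving out chromosomes with a shifted run of neighbouring genes or a shifted median were added after the data were seen. The closing section gives their effect.

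The fit was tested on simulated data with 32768 probe sets, the arrays' spread and 200 changed probe sets. With the array offsets of the data it recovered 8.96% of changes of 1.5-fold, 40.3% of 2-fold and 100% of 4-fold, with 8 false calls. Quantile normalization of the same simulated data recovered 16.4%, 68.7% and 100%, with 15 false calls. Only 200 probe sets changed in the simulation, against 7293 past the threshold in the data, so the adjusted threshold was stricter there. The simulated spread came from the unscaled arrays and already held their offsets. These shares therefore do not give the sensitivity in the data. Camera found the simulated shifted list and called 0 other lists, but the genes of that simulation varied independently and without array offsets. This check therefore cannot tell how often camera calls a list falsely in the data. The number of arrays, 2 per group, limits the precision of every value.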

Results

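Gene expression was measured in 2 clones of the Burkitt lymphoma line Raji, a DLEU1-downregulated clone made with TALENs and a wild-type control clone, each on 2 arrays with 54613 probe sets. The median intensity was 22.6 and 18.4 on the control arrays and 18.7 and 20 on the DLEU1-downregulated arrays. The trimmed mean intensity was 163 and 131 against 172 and 197, so control replicate 2 was the dimmest array. Log2 values correlated across probe sets at 0.988 between the control arrays, 0.990 between the DLEU1-downregulated arrays and 0.959 to 0.961 between arrays of different clones. The log2 ratio of 3' to 5' signal, a sign of RNA integrity, was -0.17 and -0.16 against -0.10 and -0.16 for GAPDH, and 0.47 and 0.68 against 0.52 and 0.48 for ACTB. Each genotype was represented by 1 clone, and the p-values measure only the spread between these arrays, which may be technical.

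DLEU1, a long non-coding RNA gene of the 13q14 region that is often deleted in chronic lymphocytic leukaemia, was lower on both arrays of the downregulated clone. Its probe set read 1363.4 and 1023.8 on the control arrays and 523.7 and 616.9 on the DLEU1-downregulated arrays. The mean intensity was 1194 ± 240 against 570.3 ± 65.9 (SD, n = 2 arrays each), a 2.09-fold difference. The log2 change was -1.04 ± 0.24 (SE) with a limma adjusted p = 3.2e-04, and -1.38 with adjusted p = 2.74e-06 after quantile normalization. An exact two-sided permutation test gave p = 0.333, the smallest value that 6 assignments of 4 arrays allow. The call was lost without either array of the downregulated clone but not without either control array, and each of these fits leaves 1 array in a group. The log2 change itself stayed at -0.92 without replicate 1 of the downregulated clone and -1.15 without its replicate 2. It was -0.83 without control replicate 1 and -1.24 without control replicate 2.

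Of 18 tested members of the 13q14 list, DLEU1 included, 4 rose and 2 fell, DLEU1 among them (4 and 2 adjusted over the list alone, 4 and 6 after quantile normalization), and camera made no call (adjusted p = 0.806). KPNA3, an adaptor of nuclear import, rose from a mean intensity of 1331 to 2855 (log2 change 1.09, adjusted p = 9.63e-06). RNASEH2B, a subunit of ribonuclease H2, rose by 1.16 (adjusted p = 1.29e-04) in its brightest probe set, and its other 3 tested probe sets did not pass. EBPL, a relative of a sterol isomerase, rose by 0.66, and DHRS12, a member of the short-chain dehydrogenase family, rose by 0.80. SETDB2, a histone methyltransferase, fell by 0.65 (adjusted p = 0.0472) in its brightest probe set, and its other 5 tested probe sets did not pass. DLEU2, the non-coding gene that overlaps the beginning of DLEU1 and hosts a microRNA cluster, had a log2 change of -0.14 in its brightest probe set (adjusted p = 0.741), and -0.49 after quantile normalization (adjusted p = 7.17e-04). A dimmer DLEU2 probe set went the other way, by 0.70 (adjusted p = 0.0511) and by 0.69 after quantile normalization (adjusted p = 0.0371). Both carry the suffix _x_at, and the remaining DLEU2 probe sets passed on neither scale. TRIM13, a ubiquitin ligase gene that overlaps DLEU2, differed between its probe sets. Its brightest probe set had a log2 change of 0.03 (adjusted p = 0.953) that turned to -0.31 after quantile normalization (adjusted p = 0.0111), while 3 dimmer ones rose by 0.86 to 0.99. The tumour suppressor RB1 had a log2 change of 0.28 (adjusted p = 0.440). The remaining tested genes of the list, KCNRG, SPRYD7, ARL11, RCBTB1, CAB39L, CDADC1, FAM124A, INTS6 and WDFY2, did not pass in their brightest probe sets, and DLEU7 and GUCY1B2 were too dim to be tested. A dimmer INTS6 probe set rose by 0.78 (adjusted p = 0.0179), against -0.23 in the brightest, and the remaining INTS6 probe sets did not pass. The list's median was 0.09 and its mean 0.10, while camera's direction was down. Genes of chromosome 13 as a whole had a median log2 change of -0.16 after quantile normalization and removal of the trend with brightness.

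In the downregulated clone, several NF-kB target genes were higher and several germinal centre genes lower. The chemokine CCL22 was 16.3-fold higher on its arrays (mean intensity 222.9 against 3632), and 25 of 34 tested NF-kB targets rose while 2 fell (camera adjusted p = 2.83e-10). The germinal centre regulator BCL6 fell from 3105 to 1121 and the B-cell oncogene TCL1A from 3190 to 695.4. Camera also placed MYC targets (adjusted p = 1.15e-04), respiratory chain genes (adjusted p = 1.15e-04) and cholesterol synthesis genes (adjusted p = 0.00393) above other genes, and each of these lists, NF-kB targets included, had adjusted p = 0.993 with an estimated correlation. All 30 lists had this same value with an estimated correlation, so it does not set the lists apart. All log2 changes below are for the values as deposited, whose median over all tested probe sets was 0.16, and 0.01 after quantile normalization.

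Of 32768 probe sets tested, 7293 passed the threshold, 5620 of them higher and 1673 lower in the downregulated clone, so that 77.1% rose. After quantile normalization 11083 passed, 5591 higher and 5492 lower (50.4% rose). Of these, 5204 rose and 1578 fell on both scales, and limma found 0 that passed in opposite directions on the 2 scales. A change of at least 2-fold was met by 1796 rises and 654 falls, or 835 and 1018 after quantile normalization. The count depended on single arrays, with 8463 probe sets without control replicate 1, 4801 without control replicate 2, 1763 without DLEU1-downregulated replicate 1 and 1060 without DLEU1-downregulated replicate 2. Poly-A spike-ins, which are foreign transcripts added to the RNA before labelling, read higher on the downregulated arrays by a mean log2 difference of 0.26. Hybridisation spike-ins, added after labelling, differed by -0.084. By gene, 2701 of 13284 rose and 762 fell as deposited. The list counts below are to be read against these shares, and a list near them does not stand out from all genes.

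Ranked by log2 change, the 10 largest rises, after CCL22, were led by MAP7D2, a microtubule-associated protein (13.7-fold, 154.9 to 2129), and SPARCL1, a secreted matrix glycoprotein (11.7-fold, 49.65 to 580.1). By the ratio of mean intensities BBOX1 (42.6-fold) would come before CCL22, and PYGB (12.5-fold) before SPARCL1. CDK2AP1, which binds and restrains a cell cycle kinase, rose from 300.4 to 2183, and STAG3, a cohesin subunit of meiosis, from 178.4 to 1157. IL10, an immunosuppressive cytokine, rose 9.53-fold from 20.4 to 194.4. Its control level lay near the median intensity of the control arrays (22.6 and 18.4). Without detection calls it is unknown whether that level was above background, so the fold is uncertain. The list was completed by BBOX1, of carnitine synthesis (log2 change 2.96, from a control mean of 3.1), PLXNA1, a semaphorin receptor (2.66), PYGB, a glycogen phosphorylase (2.58), and CTTN, an organiser of branched actin (2.49). Among the 10 largest falls, GNB4, a G-protein beta subunit, fell from 595.1 to 10.6 and the G-protein-coupled receptor GPR18 from 539.7 to 19.75. The log2 change of GNB4 was -4.51, with limma adjusted p = 8.36e-66 as deposited and 2.3e-07 after quantile normalization. S100A10, a partner of annexin A2 at the plasma membrane, fell 16.1-fold from 549.2 to 34.05. GATM, of creatine synthesis, fell from 325 to 15.95, SCRN1 from 238.2 to 13.2 and GJC1, a gap junction connexin, from 238.3 to 6.45. SETBP1, a SET-binding nuclear protein (log2 change -3.80), PWAR6, a non-coding transcript of the imprinted Prader-Willi region (-3.21), ZNF385B, a zinc finger protein (-3.17), and CCDC85A (-3.05) completed the falls. For BBOX1 and PYGB in the control clone, and for GNB4, GJC1, GATM, SCRN1, SETBP1, PWAR6, ZNF385B and CCDC85A in the downregulated clone, the mean lay under the added 16, so the log2 change is set in part by that number. Standard errors of these 20 changes were 0.24 to 0.27, and after quantile normalization the rises ranged from 2.25 to 3.60 and the falls from -4.64 to -3.14.

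**Figure D1:**
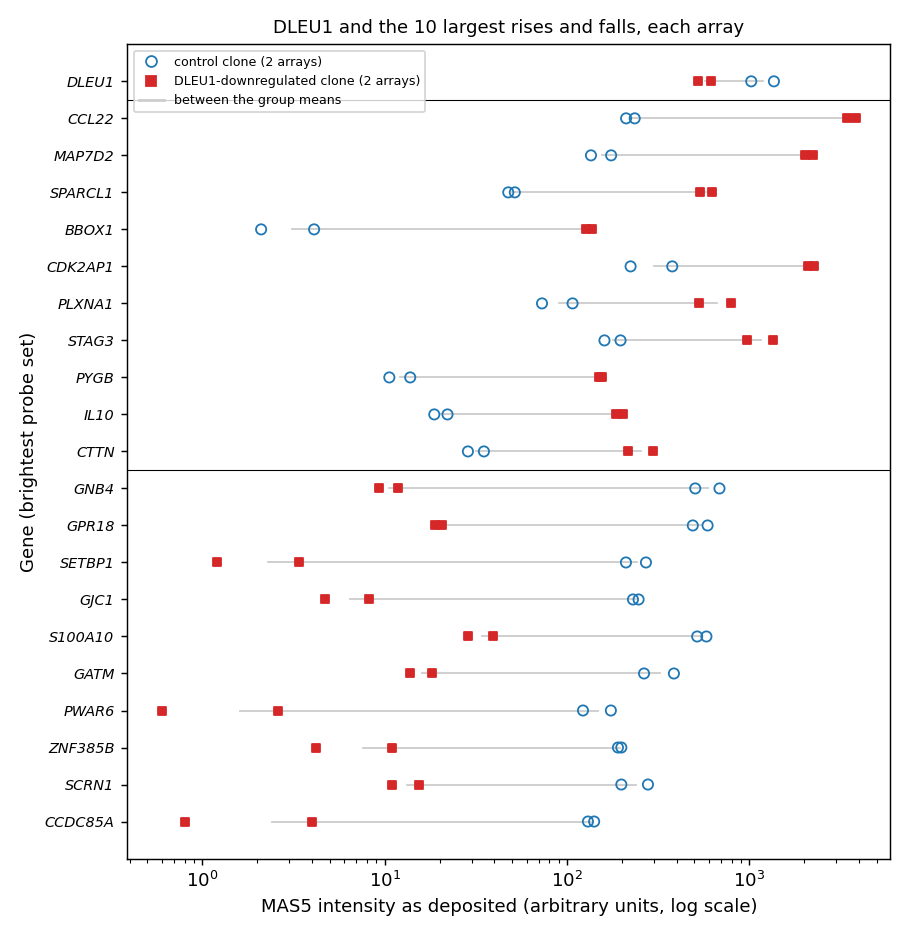
MAS5 intensity as deposited (arbitrary units, log axis) of DLEU1 and of the 10 genes with the largest rise and the 10 with the largest fall, 1 row per gene, with open circles for the 2 control arrays, squares for the 2 DLEU1-downregulated arrays and a grey line between the group means. In every row both arrays of a clone lie on the same side of the other clone's arrays, as for CCL22 at means of 222.9 and 3632 and for GNB4 at 595.1 and 10.6. For every gene but DLEU1 this was a condition of the choice.

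Of 34 NF-kB targets tested, 25 rose and 2 fell (26 and 2 adjusted over the list alone), and camera placed the list above other genes with adjusted p = 2.83e-10, but with adjusted p = 0.993 with an estimated correlation. The smallest p-values after CCL22 belonged to CCL5, another chemokine (48.35 to 286.1), NFKBIA, the inhibitor that NF-kB induces (1098 to 3548), and EBI3, a cytokine subunit first seen in virus-infected B cells (log2 change 1.75). Of 22 germinal centre genes, 1 rose and 9 fell (2 and 10 adjusted over the list alone, 1 and 14 after quantile normalization), with camera adjusted p = 4.80e-04 and adjusted p = 0.993 with an estimated correlation. Beside BCL6, the adaptor STAP1 fell by 1.44 and the G-protein regulator RGS13 fell from 4823 to 2600, whereas SERPINA9, a serpin named for germinal centre B cells, rose from 399.2 to 1773. Of 27 B-cell identity genes, 3 rose and 5 fell (3 and 7 adjusted over the list alone, 3 and 16 after quantile normalization), and camera called the list lower (adjusted p = 0.0177, and adjusted p = 0.993 with an estimated correlation). Its median was 0.01 and its mean -0.17, and the call was lost with no filter on dim probe sets (adjusted p = 0.0505) and without chromosomes 6, 7, 8, 11 and 20, which held a shifted run of genes or had a shifted median (adjusted p = 0.0793 as deposited, but 0.00847 after quantile normalization). The fallen members were led by TCL1A, the receptor-like FCRL1, measured by a probe set prone to cross-hybridisation (-1.59), the surrogate light chain gene VPREB3 (-1.47) and the chemokine receptor CXCR5 (-1.38).

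Lists of B-cell signalling and of plasma cells were not called as deposited. Of 30 B-cell receptor signalling genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, 6 and 14 after quantile normalization, camera adjusted p = 0.815). PIK3CD, a lipid kinase of leukocytes (1182 to 3217), the inhibitory receptor FCGR2B (log2 change 0.95) and the exchange factor VAV2 (0.81) rose, and LILRB1, an inhibitory receptor measured by a cross-hybridising probe set, fell by 2.09. Of 17 plasma cell genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, 3 and 7 after quantile normalization, camera adjusted p = 0.260). FKBP11, a secretory chaperone, rose from 2806 to 5653, while CD38, a surface enzyme of germinal centre and plasma cells (1368 to 644.6), XBP1, a driver of secretory capacity (1898 to 949), and CAV1, the coat protein of caveolae (-1.28), fell. Among 14 complement regulators and antibody targets, 2 rose and 2 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.242). After quantile normalization 1 rose and 8 fell (camera adjusted p = 0.00971, and adjusted p = 0.332 with an estimated correlation). The receptor CD40 rose from 663.5 to 1430 and CD70, a ligand of B and T cells, by 0.59, while the complement receptor CR1 fell by 1.29.

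Of 44 MYC targets, 23 rose and limma found 0 that fell (29 and 0 adjusted over the list alone, 31 and 1 at unadjusted p under 0.05, 24 and 5 after quantile normalization), with camera adjusted p = 1.15e-04 and adjusted p = 0.993 with an estimated correlation. SLC29A1, a nucleoside transporter (253.1 to 1004), SRM, an enzyme of spermidine synthesis (1656 to 4237), POLR3G, an RNA polymerase subunit (310.1 to 986.4), and MYBBP1A, a nucleolar protein (228.6 to 582), rose, and MYC itself, named after its value was seen, had a log2 change of 0.03 (adjusted p = 0.941). Of 53 oxidative phosphorylation genes, 19 rose and limma found 0 that fell (32 and 0 adjusted over the list alone, 35 and 0 at unadjusted p under 0.05, 20 and 2 after quantile normalization), with camera adjusted p = 1.15e-04 and adjusted p = 0.993 with an estimated correlation. The complex I subunits NDUFB2 (3175 to 6930), NDUFB10 (1982 to 4622), NDUFA8 (1423 to 3144) and NDUFA10 (929 to 1864) had the smallest p-values. For cholesterol biosynthesis, 11 of 19 genes rose and limma found 0 that fell (15 and 0 adjusted over the list alone, 15 and 0 at unadjusted p under 0.05, 11 and 1 after quantile normalization), with camera adjusted p = 0.00393 and adjusted p = 0.993 with an estimated correlation. The lanosterol synthase LSS (1009 to 2363), the mevalonate pathway enzyme MVD (31.3 to 112), the sterol carrier STARD4 (558.4 to 1069) and the sterol sensor INSIG1 (1496 to 2555) rose.

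Of 14 heat shock genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00613 and adjusted p = 0.993 with an estimated correlation. The co-chaperones DNAJA1 (2156 to 5732), HSPH1 (2188 to 4961) and DNAJB1 (222.8 to 550.6) rose, and DNAJB4, of the same family, fell from 646.7 to 225.4. In the unfolded protein and integrated stress response list, 14 of 35 rose and 5 fell (15 and 5 adjusted over the list alone, 13 and 15 after quantile normalization), and camera made no call (adjusted p = 0.422). The endoplasmic reticulum factors CRELD2 (681.2 to 2652), PDIA4 (1007 to 2636), HSPA5 (3653 to 7371) and SDF2L1 (713.4 to 1775) rose. Of 30 glycolysis and hypoxia genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.899, direction up). After quantile normalization 8 rose and 8 fell (camera adjusted p = 0.907, direction down). The aldolases ALDOC (319.6 to 915.2) and ALDOA (a cross-hybridising probe set, log2 change 0.71) and the hexokinase HK2 (512.6 to 1029) rose, and DDIT4, an mTOR inhibitor induced by hypoxia, fell from 621.1 to 303.4. Of 42 cytosolic ribosomal protein genes, limma called 0 (0 at unadjusted p under 0.05, 0 adjusted over the list alone), and 9 fell after quantile normalization. Camera made no call for this list as deposited (adjusted p = 0.242) or after quantile normalization (0.0720), but called it lower after median centring (8.77e-06), with a common trimmed mean (1.34e-05) and with the filter on dim probe sets at the 60th percentile (0.0386). With an estimated correlation it had adjusted p = 0.993 as deposited and 0.384 after quantile normalization. The smallest p-values were those of RPS25 (log2 change 0.27), RPL24 (-0.12), RPLP2 (0.21) and RPS15 (0.09).

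For the cell cycle, genes were tested by phase. Of 45 genes of the G1/S transition and DNA replication, 17 rose and 1 fell (21 and 2 adjusted over the list alone, 18 and 6 after quantile normalization), with camera adjusted p = 0.0110 and adjusted p = 0.993 with an estimated correlation. The camera call was lost after quantile normalization (adjusted p = 0.0685), with the filter on dim probe sets at the 60th percentile (adjusted p = 0.134) and without chromosomes 6, 7, 8, 11 and 20 (adjusted p = 0.0608). Outside these chromosomes 9 of 31 tested members rose and 1 fell, and the other 14 members lie on them. The clamp loader RFC2 (198.4 to 684.4), the helicase subunit MCM7 (1681 to 3705), the histone chaperone CHAF1B (81.45 to 217.3) and GINS1, of the replication fork (1393 to 2785), rose. Of 51 genes of G2/M and mitosis, 3 rose and 2 fell as deposited (2 and 2 adjusted over the list alone, camera adjusted p = 0.283). After quantile normalization 4 rose and 33 fell, and camera called the list lower (adjusted p = 2.96e-05, and adjusted p = 0.332 with an estimated correlation). The kinetochore protein NDC80 (1601 to 729.2) and the phosphatase CDC25C (181.1 to 81.55) fell, and the ubiquitin-conjugating enzyme UBE2C (1404 to 2646) and the transcription factor FOXM1 (a cross-hybridising probe set, 430.7 to 888.2) rose. Of 10 replication-dependent histone genes, 5 fell and limma found 0 that rose (5 and 0 adjusted over the list alone, 6 and 0 at unadjusted p under 0.05, 7 and 0 after quantile normalization), with camera adjusted p = 4.14e-08 and adjusted p = 0.993 with an estimated correlation. They were led by H2AC6 (653.6 to 65.55) and the linker histone H1-2 (249.6 to 32.75), followed by H2BC5, measured by a cross-hybridising probe set (-0.98), and H2AC17 (-0.86). Of its 10 genes, 9 lie on chromosomes 6, 7, 8, 11 and 20, and too few members were left for a test without them. These chromosomes were left out whole, so the 9 genes need not lie in a shifted run. Of 33 double-strand break repair genes, 5 rose and 2 fell (8 and 2 adjusted over the list alone, 8 and 13 after quantile normalization, camera adjusted p = 0.931). NBN, a sensor of breaks (1140 to 2778), the end-joining kinase PRKDC (0.65) and RAD54B, of homologous recombination (0.78), rose, and the helicase WRN fell from 217 to 102.5. Of 24 immediate early genes, 6 rose and 2 fell (9 and 4 adjusted over the list alone, 6 and 6 after quantile normalization, camera adjusted p = 0.931). The transcription factor EGR1 fell from 207.8 to 58.05, whereas KLF10, induced by TGF-beta (487.9 to 1096), the phosphatase DUSP5 (166.4 to 391.6) and the chemokine CCL4 (358.1 to 774) rose.

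Genes of apoptosis moved in both directions. Of 19 pro-apoptotic genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone, 8 and 7 after quantile normalization, camera adjusted p = 0.931). The BH3-only gene HRK (171.4 to 56.55) and the mitophagy receptor BNIP3L (1171 to 478.9) fell, while BID (374.6 to 930) and BAD (114.3 to 279.9), which also carry a BH3 domain, rose. Of 17 anti-apoptotic genes, 7 rose and limma found 0 that fell (7 and 1 adjusted over the list alone, 8 and 1 at unadjusted p under 0.05, 7 and 5 after quantile normalization), and camera made no call (adjusted p = 0.104), but called the list higher with no filter on dim probe sets (adjusted p = 0.00459). With an estimated correlation the list had adjusted p = 0.993 as deposited and 0.687 after quantile normalization. BCL2A1, a survival gene driven by NF-kB (525.4 to 1646), the NF-kB feedback inhibitor TNFAIP3 (1222 to 3160), the caspase inhibitor CFLAR (a cross-hybridising probe set, 303.4 to 808.1) and the apoptosis inhibitor API5 (785.6 to 1594) rose. Of 15 death receptor genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, 4 and 3 after quantile normalization, camera adjusted p = 0.428). The adaptors TRAF1 (153.9 to 555) and TRADD (115.5 to 242.6) and the receptor TNFRSF1B (70.9 to 186.8) rose, and TNFSF10, the ligand TRAIL, fell from 98.35 to 38.1. Of 26 p53 targets, 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.173). After quantile normalization 4 rose and 12 fell (camera adjusted p = 0.00613, but 0.378 with an estimated correlation and 0.109 without chromosomes 6, 7, 8, 11 and 20). TP53INP1, an inducer of cell death, fell from 635 to 66 and the stress sensor SESN2 from 272.7 to 129.2, while the kinase PLK3 (22.7 to 75.9) and the zinc finger gene ZMAT3 (1304 to 2426) rose.

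Of 20 genes of MHC class I antigen presentation, 11 rose and limma found 0 that fell (12 and 0 adjusted over the list alone, 13 and 0 at unadjusted p under 0.05, 11 and 3 after quantile normalization), with camera adjusted p = 0.00393 and adjusted p = 0.993 with an estimated correlation. The peptide transporter TAP1 (428.8 to 1211), the loading factor TAPBP (610.4 to 1333) and the chaperones PDIA3 (644.6 to 2694) and CALR (a cross-hybridising probe set, 1189 to 2658) rose. Of 14 MHC class II genes, 2 rose and limma found 0 that fell (2 and 0 adjusted over the list alone, 3 and 1 at unadjusted p under 0.05, camera adjusted p = 0.841). After quantile normalization 2 rose and 8 fell (camera adjusted p = 0.0431, and adjusted p = 0.332 with an estimated correlation), and 10 of the 14 lie on chromosomes 6, 7, 8, 11 and 20, which left too few for a test without them. Those chromosomes were left out whole, so the 10 genes need not lie in a shifted run. The invariant chain CD74 (2921 to 5582) and the protease LGMN (101 to 263.4) rose, and the peptide-loading modulator HLA-DOB had a log2 change of -0.62 and the master regulator CIITA one of 0.53. Of 35 interferon-stimulated genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone, 10 and 9 after quantile normalization, camera adjusted p = 0.978). IFIT3 (82.85 to 496.8) and IFIT5 (32.75 to 114), which bind viral RNA, the virus tether BST2 (296.2 to 746.2) and XAF1, an antagonist of apoptosis inhibitors (39.55 to 114.3), rose.

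Of 12 T and NK cell markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.428). The T-cell receptor constant gene TRBC1 (344.4 to 1689), the receptor chain CD247 (29.5 to 102.1) and the adaptor TRAT1 (11.2 to 49.3) rose and the kinase LCK fell by 0.86, while the receptor chains CD3D and CD3E, chosen after their values were seen, had log2 changes of -0.25 and -0.09 that did not pass. Of 10 myeloid markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.817). The fungal receptor CLEC7A rose from 52 to 343.9 and the granule protease CTSG fell by 0.93, while the membrane protein MS4A7 and the integrin ITGAM had log2 changes of -0.27 and 0.24. Of 13 stromal and epithelial markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.104), and camera called the list lower without DLEU1-downregulated replicate 1 (adjusted p = 0.0161). With an estimated correlation the list had adjusted p = 0.993 over all arrays, and 0.687 after quantile normalization. VIM, an intermediate filament gene also active in lymphocytes, rose from 704.9 to 3210, and CAV1, the collagen gene COL1A2 (-1.14) and the actin gene ACTA2 (-0.73) fell. Of 7 erythroid markers, limma called 0 (0 at unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.256). AHSP, a haemoglobin chaperone (-0.46), the anion exchanger SLC4A1 (-0.43), the embryonic globin HBE1 (-0.30) and the transcription factor GATA1 (0.24) had the smallest p-values.

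**Figure D2:**
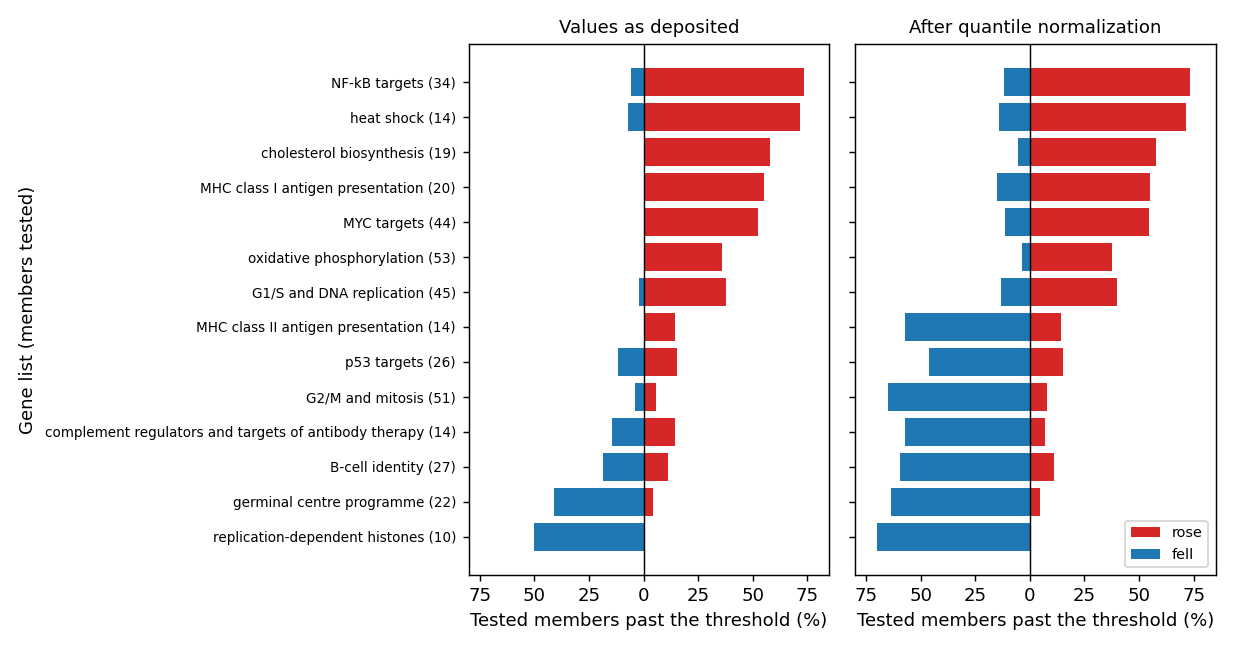
Percent of each list's tested members past the threshold (x axis, bars to the right for genes that rose and to the left for genes that fell in the DLEU1-downregulated clone) for the 14 lists that camera called as deposited or after quantile normalization, with the values as deposited on the left and after quantile normalization on the right. NF-kB targets had 25 rises in 34 genes on both scales, while G2/M genes had 2 falls as deposited and 33 after quantile normalization.

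Camera called 10 of the 30 lists as deposited and 13 after quantile normalization. With an estimated correlation camera called 0 lists (0 at unadjusted p under 0.05, smallest unadjusted p = 0.124), and fry, which tests each list on its own, also called 0 (3 at unadjusted p under 0.05). The correlation was estimated from 2 arrays per group, which makes the estimate poor. It was 0.45 for NF-kB targets and 0.93 for oxidative phosphorylation, against the preset 0.01. The adjusted p = 0.993 was shared by all 30 lists and does not set them apart. Median, mean and camera direction also differed in sign for the pro-apoptotic, p53, B-cell receptor, complement, G2/M, interferon, MHC class II, ribosomal, immediate early and myeloid lists.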

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

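No test was run on the values in this part, which come from control probe sets outside the comparison and were picked out because they were at least 2-fold higher, by geometric means, with both DLEU1-downregulated arrays above both control arrays and a mean intensity over 16. Control probe sets for 18S ribosomal RNA were higher by 3.43-fold at the 5' end and by 3.60-fold in the middle. Outside these conditions, the probe set at the 3' end of the same RNA was higher by 1.73-fold, and those for 28S ribosomal RNA by 1.00-fold to 1.38-fold. Not all control probe sets are covered here.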

How the results depend on the processing

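The 4 alternatives named as added in the description of the processing were chosen after the data were seen, and the others before. Count of probe sets past the threshold (7293): 4395 with no filter on dim probe sets, 4482 at adjusted p under 0.01, 11083 after quantile normalization, 11408 after median centring and 11394 with a common trimmed mean. The lower threshold acts by construction. With no filter the prior degrees of freedom also fell from infinite to 10.97, and with the scalings to between 6.62 and 6.80. The count stayed within 1.5 times at 9314 for adjusted p under 0.1, 6641 with the filter at the 60th percentile, 7142 without a trend, 6649 without _x_at probe sets, 7185 and 7314 with pseudocounts of 1 and 64, and 9835 after quantile normalization without the dimmest array. The share that rose (77.1%) was 50.4% after quantile normalization, 55.8% after median centring and 44.9% with a common trimmed mean. The count with at least 2-fold change (2450) was 3765 with a pseudocount of 1 and 1093 with 64, which act on dim probe sets by construction. Leaving out each array gave counts of 1060 to 8463 (2-fold, 1057 to 3621), shares of 52.3% to 88.3% and DLEU1 changes of -1.24 to -0.83. Leaving an array out makes the lone array of its clone vary like the others by assumption. The 10 gene list calls became 0 with an estimated correlation, 0 with fry (3 at unadjusted p under 0.05) and 0 with quantile normalization and an estimated correlation (1 at unadjusted p under 0.05), and ranged from 7 (without chromosomes 6, 7, 8, 11 and 20) to 14 (common trimmed mean) otherwise, with 10 from the mean of a gene's probe sets. At the preset correlation camera also called lower the G2/M list after median centring (adjusted p = 0.00812), with a common trimmed mean (5.60e-04) and with the filter at the 60th percentile (0.0417), the p53 list in the last 2 (0.0212 and 0.0361), and the complement list with a common trimmed mean (0.0250). The brightest TRIM13 probe set reversed to -0.31 after quantile normalization and -0.29 with a common trimmed mean. Of the named-gene results, 69 lost their call without DLEU1-downregulated replicate 2 and 42 without replicate 1, against 9 or fewer in every scaling, filter and pseudocount setting. Beyond what is stated, the cause was not tested. Signal over background limits dim probe sets, of which 21845 were not tested.

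Same-numbered arrays did not deviate together (correlation of deviations -0.0525), so the numbers pair nothing known. With the replicate block 1901 probe sets passed, 65.9% of them higher, DLEU1 stayed at -1.04 with adjusted p = 0.162, 51 named-gene results lost their call, and camera at the preset correlation also called the stromal and epithelial list (adjusted p = 0.0356).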

Other observations

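The tests of the poly-A spike-ins, the hybridisation spike-ins and the cross-hybridising probe sets were chosen after the result was seen. So were those of the number of clones and of the brightness of neighbouring genes. Camera without the shifted chromosomes and scaling to a common trimmed mean were also added after the data were seen. The tests of the flanking genes, the largest run of neighbouring genes and a general rise of messenger RNA were chosen before. The tests of chromosome medians and the spike-in checks on other scales or without single arrays are not to be read as fixed beforehand.

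An imprinted cluster on chromosome 15, active on the paternal copy, is the region lost in Prader-Willi syndrome. Most of its tested probe sets were much lower in the downregulated clone. Of its 21 probe sets, 10 were tested, 8 fell and limma found 0 that rose, with a median log2 change of -3.06. The fallen probe sets read at most 61.1 on either DLEU1-downregulated array and at least 57.3 on either control array. PWAR6, one of the 10 largest falls, belongs to this cluster, and the fallen probe sets that do not name PWAR6 alone name several overlapping genes. The cluster gene NPAP1, with a dim probe set of its own, did not pass (log2 change -0.24, limma adjusted p = 0.639). MKRN3, NDN and MAGEL2 were too dim to be tested. These genes were named after their values were seen. The fall was therefore not shown for every gene of the cluster.

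Loss of 1 whole copy of the region would lower its neighbours too, yet the 9 tested flanking genes had a median log2 change of 0.30 after quantile normalization (SD 0.66), with 3 that rose and 2 that fell. TJP1 had the lowest value, -1.30, and UBE3A, which lies next to the cluster, had -0.14 (both named after their values were seen). Cross-hybridisation is also unlikely as the whole cause, since 2 of the fallen probe sets name only PWAR6 and carry no cross-hybridisation suffix. A difference between the clones that has nothing to do with DLEU1 cannot be told apart from an effect of DLEU1, because there was 1 clone per genotype. A small deletion inside the cluster, loss of the paternal copy with a second maternal copy, and silencing were not tested.

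Whole stretches of chromosomes shifted together. Among 13242 genes with a place, after quantile normalization and removal of the trend with brightness, the median log2 change was 0.31 over 635 genes of chromosome 7 (279 rose and 59 fell) and 0.30 over 375 genes of chromosome 20 (159 rose and 20 fell). In the 4 pairings of a downregulated with a control array these medians stayed between 0.29 and 0.37 for chromosome 7 and between 0.30 and 0.32 for chromosome 20. Of 23 chromosomes, 13 had an adjusted permutation p under 0.05, where 1e-04 is the smallest that 10000 permutations can give. Chromosome 13, which carries DLEU1, had the lowest median, -0.16 over 241 genes (35 rose and 72 fell, adjusted permutation p = 6.57e-04). Chromosomes 4 and 18 lay close to it, each at -0.145 (adjusted permutation p = 3.83e-04 and 0.00201), so a low median was not particular to chromosome 13. Its lowest run of neighbouring genes, -0.31, was no larger in size than the largest run of the shuffles, 0.42. Runs of 51 neighbouring genes from TIMM10B to COPB1 on chromosome 11 and from SLC39A14 to DCTN6 on chromosome 8 had medians of -0.67 and -0.59, and the run from CT66 to RSBN1L on chromosome 7 one of 0.62.

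A difference in gene dosage between the clones is a candidate explanation. The largest run, 0.67 in size, exceeded the largest run of 1000 shuffles of gene order, 0.42. Brightness of the probe sets is unlikely as the cause, since neighbouring genes' changes correlated at 0.136, against at most 0.0341 in 1000 shuffles among genes of like brightness, which keep any effect of brightness (a correlation across genes, which are not independent replicates). DNA copy number was not measured, and the timing of any such difference relative to the editing is unknown. Without chromosomes 6, 7, 8, 11 and 20, taken for a run beyond all shuffles of gene order or a median of at least 0.25 in size (the run of chromosome 6, -0.43, was no larger than the largest run of 0.45 in the shuffles among genes of like brightness), camera at the preset correlation called 7 lists, with adjusted p = 1.99e-14 for NF-kB targets (over all genes, adjusted p = 0.993 with an estimated correlation).

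Rises made up 77.1% of the probe sets past the threshold as deposited, against 50.4% after quantile normalization, 55.8% after median centring and 44.9% with a common trimmed mean. As deposited, the poly-A spike-ins were higher on the downregulated arrays by 0.26 (SD over 24 probe sets 0.094), as more labelled target on those arrays would give. This value ran from 0.117 without control replicate 2 to 0.410 without control replicate 1. It was 0.063 after median centring and -0.057 with a common trimmed mean. The reading therefore holds only for the deposited scale, whose target intensity is unknown. The hybridisation spike-ins, at -0.084 as deposited (-0.165 to -0.002 when each array was left out), make a brighter hybridisation or scan unlikely on that scale. They differed by -0.285 after median centring and by -0.407 with a common trimmed mean, so the size of this difference also depends on the scale. A general rise of messenger RNA beyond the spike-ins stays open. Genes as bright as the poly-A spike-ins shifted by 0.098 more on average, by 0.019 to 0.166 for the 4 spike-in transcripts and by 0.062 to 0.129 when each array was left out, and the average lies between the 0.05 set as the most without such a rise and the 0.1 set as the least with one.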
